A study of Mus musculus with 10 samples.

How the data were processed

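Polyadenylated RNA from 10 whole placentas with attached decidua of C57BL/6 mice was sequenced in pairs of 150 bp reads, per the labels' protocols. The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled to the mapped total) with 36213 genes and 10 libraries, rounded to 2 decimals. Per the submitters' processing notes, cutadapt 1.9, FastQC and HISAT2 2.0.4 were run and the genome build was mm39. The program that computed FPKM, the gene annotation and any filter are not given in the sources used here. FPKM do not keep the number of reads, and low values did not fall on steps of whole reads, so depth is unknown and no counting interval is given. FPKM divides by transcript length, so short RNAs carry large errors, and a change in a few abundant transcripts moves all other values.

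Groups were taken from the treatment label: 5 control placentas (1 to 5) and 5 FGR placentas (6 to 10). Numbers are not shared between the groups, so no pairing was used. All pairs of libraries were compared before averaging, over coding genes with at least 200 FPKM times kilobases. Control 3 and Control 5 had an SD of the log2 ratio of 0.0509, and in rising bins of abundance the spread of their log2 ratios went from 0.08 to 0.0411, against 0.18 to 0.234 between Control 2 and Control 4. The spread of the most abundant genes exceeds what read sampling alone would leave at the depth implied by the least abundant bin, as 2 libraries of the same RNA could give. The plan had all 10 libraries as separate samples. After this pair was seen it was averaged as 1 sample, so 4 control and 5 FGR samples entered each fit, and the fit planned first is kept as an alternative.

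Genes with FPKM of at least 1 in at least 5 of the 10 libraries were tested, 13183 in all. Values were transformed to log2(FPKM + 1), with a pseudocount of 1, and compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Log2 fold changes are FGR minus control on the log2(FPKM + 1) scale, which understates changes of low genes, and are given with their SE. Group values are mean ± SD of FPKM. Other p-values come from exact permutation of the group labels, for which the smallest two-sided p is 0.00794 with all 9 samples. It is 0.0179 without 1 control sample and 0.0286 without 1 FGR sample.

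A total of 32 gene lists (20 process lists, ribosomal proteins included, and 12 cell type marker lists) were tested with limma's fry at a Benjamini-Hochberg adjusted p under 0.05 over lists with at least 5 tested members. Camera was run with an estimated correlation and with a preset correlation of 0.01. Counts of called members are given over all genes tested and adjusted over the list alone.

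Genes named in the text followed a rule. It took the 8 highest and 8 lowest log2 fold changes among called genes whose groups did not overlap, without unnamed gene models, pseudogenes, ribosomal protein genes, Y-linked genes and Xist. To these it added up to 3 called members of each list, or 2 members with the smallest p where none was called, and always Vegfa, Pgf, Flt1, Kdr, Angpt1, Angpt2, Tek, Mmp2, Mmp9, Plau and Igf2. Genes named as the most abundant members of a list or as markers in single libraries were chosen after their values were seen.

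Transcript length, GC content and biotype came from the longest transcript per Ensembl gene in GENCODE M21, which is built on GRCm38. They were matched by gene identifier for 36079 of the 36213 genes and 13175 of the tested genes, and no coordinates are given because the build differs from mm39. For the length and GC adjustment, chosen after seeing the data, each library's deviations from the gene means were fitted with smooth terms of log2 length and GC content (mgcv 1.9.3) and the fit was subtracted. It was trained on coding genes with mean FPKM above 5 outside the oxidative phosphorylation, ribosomal protein and mitochondrially encoded lists, and lengths beyond the training range were set to its ends. As another control, also chosen afterwards, each list member was set against the mean of 20 coding genes nearest in length, GC content and expression level.

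The computations were tested on simulated data with 13183 genes and 5 against 4 samples. Of genes changed by 1 on the log2 scale 84% were recovered, and 93% of those changed by 1.5, with 3.3% of calls among unchanged genes. When a length trend was simulated, 93.3% of calls fell on unchanged genes without the adjustment and 6.9% with it. That trend was the same straight line in each FGR sample, without a GC term, which is simpler than the trend in the data. In simulated lists of 25 genes, fry gave an unadjusted p under 0.05 for 4% of the unshifted lists. The simulated genes varied independently, so this does not show how fry behaves for lists whose members vary together.

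The gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. These alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter on mean FPKM of at least 5, rescaling to an equal FPKM sum, median-of-ratios factors, quantile normalization, robust moderation, no intensity trend, library weights, an exact Wilcoxon rank sum test, covariates for Y-linked and decidual transcripts, and each library left out in turn. Averaging Control 3 and Control 5 was chosen after seeing the data, and the planned fit with both as separate libraries became an alternative. Alternatives added after seeing the data were the length and GC adjustment alone, without Control 1 and with the Y-linked covariate, and fits without Control 1 and FGR 7 or without Control 3 and Control 5.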

Results

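Gene expression was measured in 10 mouse placentas at embryonic day E12.5, collected whole with the decidua, the maternal lining that faces the implanted placenta. Of these, 5 came from control dams with free access to food. The other 5, called FGR for fetal growth restriction, came from dams held from E8.5 on a 50% calorie restriction, 1.5 to 2.0 g of food per day. By its title, the study asks how expression linked to trophoblast invasion and to angiogenesis changes under this restriction. Values were FPKM for 36213 genes, so the sequencing depth of each library is unknown. Summed FPKM per library ran from 359190 to 388089 in control and from 305009 to 322049 in FGR placentas, without overlap (two-sided exact permutation test, p = 0.00794). Control 3 and Control 5 differed far less than any other pair of libraries. Over 432 abundant coding genes the SD of their log2 ratio was 0.0509, against 0.24 to 1.36 in the other 44 pairs, and 0% of these genes differed by more than 1.5-fold. By a choice made after this pair was seen, they were averaged and counted as 1 sample, which leaves n = 4 control and n = 5 FGR placentas. The labels do not say which placentas shared a dam, so p-values measure the spread between these samples.

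FGR placentas held more transcript of several prolactin-family hormones of trophoblast giant cells, the invasive polyploid cells at the border with the decidua. Prl7a1 (ENSMUSG00000006488) was at 86.7 ± 30.6 FPKM in control (SD, n = 4) and 489 ± 119 in FGR placentas (SD, n = 5), a log2 fold change of 2.51 ± 0.24 (SE; limma adjusted p = 0.00371). Prl3d1 (ENSMUSG00000057170), the placental lactogen of early giant cells, rose from 52.6 ± 16.1 to 155 ± 45.8 FPKM (log2 fold change 1.54, adjusted p = 0.0082), and Prl2c3 rose from 596 ± 176 to 1650 ± 297 FPKM (1.50, adjusted p = 0.00537). Not all abundant members of the family rose: Prl3b1 (0.06, adjusted p = 0.913) and Prl8a9 (-0.20, adjusted p = 0.741) were not called. The giant cell marker list was not called either (fry adjusted p = 0.199). Serpine1 (ENSMUSG00000037411), the inhibitor of plasminogen activators, rose from 65.7 ± 16.4 to 213 ± 35.7 FPKM (1.70, adjusted p = 0.00461). The anticoagulant gene Tfpi rose from 67.0 ± 13.1 to 202 ± 50.3 FPKM (1.56, adjusted p = 0.00465).

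The endothelial genes Angpt2, Kdr, Pecam1 and Tek were called higher, while Vegfa was not called. Angpt2 (ENSMUSG00000031465), a ligand of the endothelial receptor Tek, rose from 10.2 ± 1.51 to 22.5 ± 2.93 FPKM (log2 fold change 1.08 ± 0.12, adjusted p = 0.00465). The VEGF receptor gene Kdr rose from 3.80 ± 1.03 to 6.85 ± 0.38 FPKM (0.74, adjusted p = 0.00965). The endothelial adhesion gene Pecam1 rose from 12.6 ± 1.04 to 21.2 ± 1.89 (0.70, adjusted p = 0.00465) and Tek from 3.19 ± 0.426 to 5.15 ± 0.623 (0.55, adjusted p = 0.00826). Vegfa measured 17.2 ± 3.52 FPKM in control and 17.9 ± 1.70 in FGR placentas (adjusted p = 0.697). The Vegfa relative Pgf and the VEGF receptor gene Flt1 were not called either: Pgf had a log2 fold change of 0.20 (adjusted p = 0.21) and Flt1 of 0.49 (adjusted p = 0.228). Neither were the gelatinases, with Mmp2 at 8.15 ± 4.62 against 7.66 ± 3.77 FPKM (adjusted p = 0.968) and Mmp9 at 1.04 ± 0.621 against 1.26 ± 0.244 (adjusted p = 0.453), nor the fetal growth factor gene Igf2 at 298 ± 57.7 against 300 ± 42.1 FPKM (adjusted p = 0.941). Plau, the urokinase gene, had a log2 fold change of 0.54 with an adjusted p of 0.0466, and that call was lost without Control 1 (adjusted p = 0.0842), Control 2 (0.0565), FGR 6 (0.0983), FGR 8 (0.0888), FGR 9 (0.0951), FGR 10 (0.0612) or the averaged Control 3 and 5 (0.1). Over the 28 alternatives its adjusted p ran from 0.00836 to 0.296. Angpt1 lay below the expression filter and was not tested.

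**Figure D1:**
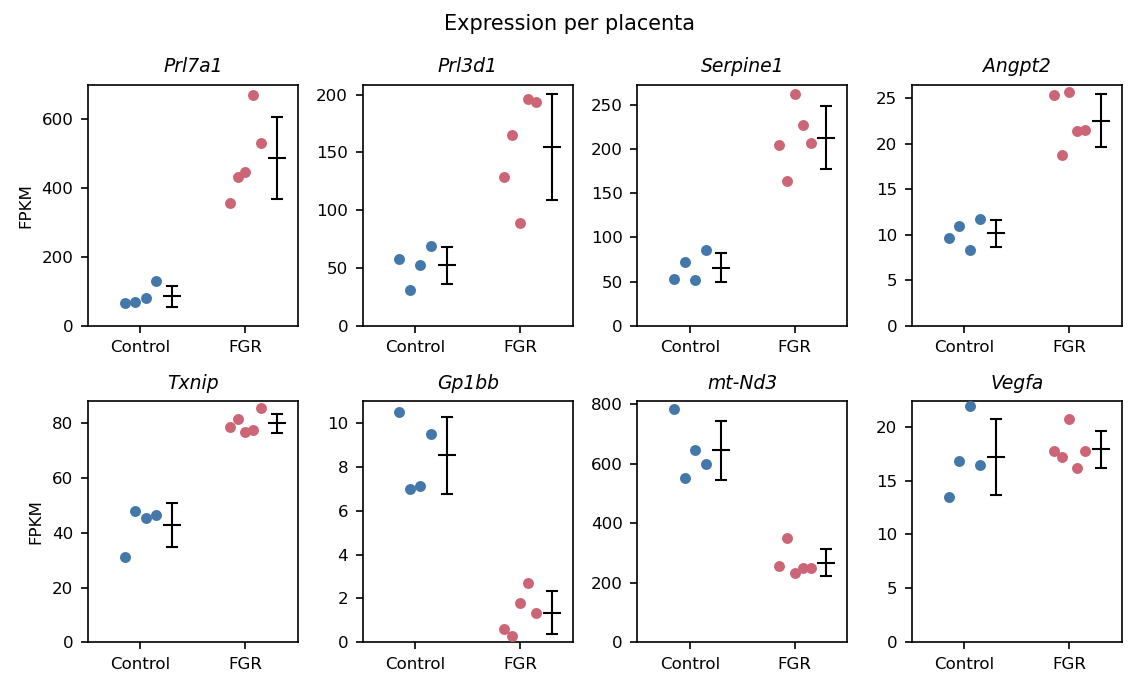
FPKM per placenta of 8 genes in 4 control samples (blue, Control 3 and Control 5 averaged) and 5 FGR samples (red), each axis starting at 0, with the mean and SD in black. All FGR values of Prl7a1, Prl3d1, Serpine1, Angpt2 and Txnip lie above the controls and those of Gp1bb and mt-Nd3 below them, while Vegfa overlaps.

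Of the other genes with the largest separated changes, Vcl, which encodes the focal adhesion protein vinculin, rose from 7.36 ± 4.06 to 23.7 ± 2.16 FPKM and the chemokine receptor-like gene Ccr1l1 from 11.2 ± 6.05 to 32.5 ± 14.6. Vcl had a log2 fold change of 1.77 (adjusted p = 0.0123), and of 1.03 after the length and GC adjustment without Control 1. Its call was lost when the Y-linked covariate was added to that adjustment of all samples (0.0597, range over its alternatives 0.000372 to 0.0597). The call of Ccr1l1 (log2 fold change 1.50, adjusted p = 0.0201) was lost with no filter (0.053) and after the length and GC adjustment without Control 1 (0.0647, range over its alternatives 0.00764 to 0.0647). Mir675 went from 1.44 ± 2.54 to 25.6 ± 10.8 FPKM, but this small RNA lies within H19 and its value is uncertain in a library of longer fragments. The lowest was Gp1bb, a platelet glycoprotein gene, which fell from 8.52 ± 1.75 to 1.36 ± 0.968 FPKM (log2 fold change -2.10 ± 0.29, adjusted p = 0.00524). Mitochondrial transcripts followed: mt-Nd3 fell from 646 ± 99.3 to 268 ± 46.2 FPKM (-1.27 ± 0.15, adjusted p = 0.00465), and mt-Nd6 fell from 1800 ± 209 to 782 ± 224. The transfer RNAs mt-Te (-1.57), mt-Ts1 (-1.38) and mt-Tg (-1.18) were also called, though RNAs this short are poorly measured by FPKM. Fdx2, a mitochondrial ferredoxin gene, and Scand1 had log2 fold changes of -1.17 and -1.16, and of -0.64 and -0.45 after adjustment for length and GC content. With that adjustment Fdx2 was not called without Control 1 (adjusted p = 0.0537) or with the Y-linked covariate (0.0796, range over its alternatives 0.00342 to 0.0796). The Prl genes belong to a large family of related copies, so reads shared between copies leave their single values uncertain.

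Across all 13183 tested genes, 4135 (31.4%) were called between the groups, 2583 higher and 1552 lower in FGR placentas, most of them by little: 2831 calls lay within 1.5-fold, and only 67 higher and 73 lower calls exceeded 2-fold. Groups did not overlap for 4271 genes (32.4%, where chance gives 1.59%). The median log2 fold change of all genes was 0.10, and it was 0.33 with each library rescaled to an equal sum and 0.02 with median-of-ratios factors. The share of calls that were higher moved with this choice, from 62.5% as deposited to 88.5% and 51.5%. Leaving out FGR 9 gave 2522 calls and leaving out FGR 10 gave 2612, and leaving out FGR 6 gave 1692 higher calls.

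Fold changes followed transcript length. Coding transcripts under 1000 nucleotides had a median log2 fold change of -0.54 and those of 6000 or more had 0.36, oxidative phosphorylation, ribosomal protein and mitochondrial genes left aside. The trend separated the libraries: the slope of a library's values per doubling of transcript length was -0.301 to -0.059 in controls and 0.065 to 0.165 in FGR placentas (two-sided exact permutation test, p = 0.00794). After each library was adjusted for length and GC content, 1735 genes were called, 885 higher and 850 lower (51.0% higher), and 1140 of them were also called in the same direction without the adjustment. Of the calls made without it, only 25.7% of the higher and 30.7% of the lower were kept. Prl7a1 (2.70), Prl3d1 (1.84), Serpine1 (1.60), Angpt2 (0.85), Kdr (0.39), Pecam1 (0.53), Gp1bb (-1.89) and mt-Nd3 (-0.75) stayed called with these adjusted log2 fold changes. Kdr was lost when the Y-linked covariate was added to the adjustment (adjusted p = 0.0691, range over its alternatives 0.000457 to 0.0691). So were Vcl, mt-Nd6, Fdx2, Itgav, Gbe1, Nupr1, Sec61b, Sel1l, Sgk1, Errfi1, Atp5e, Ndufa2, mt-Co3, Lipg, Lamb1, Ccn1, Fos, Krt7 and Rpl36 (adjusted p from 0.054 to 0.109). Adjusted without Control 1, Ccr1l1, mt-Nd6, Fdx2, Gbe1, Sel1l, Errfi1 and Ccn1 were lost (0.0537 to 0.0772). Other named genes stayed called after the adjustment alone with log2 fold changes smaller by more than 1.5 times: mt-Nd6 (-0.74), mt-Co3 (-0.59), Ndufa2 (-0.57), Rpl36 (-0.44), Sec61b (-0.26), Sel1l (0.24), Gbe1 (0.35), Sfmbt2 (0.66) and Lamc1 (0.52). Krt7 moved the other way, to -0.54. In contrast, Tek (0.24, adjusted p = 0.216, range over its alternatives 0.00187 to 0.23), Plau (0.48, adjusted p = 0.141), mt-Ts1 (-1.05, adjusted p = 0.0817) and mt-Tg (-0.62, adjusted p = 0.204) were no longer called.

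**Figure D2:**
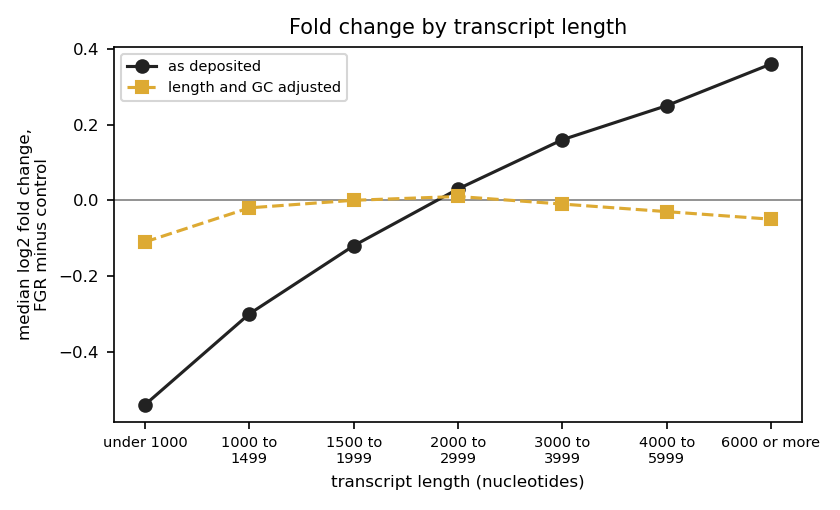
Median log2 fold change (FGR minus control) of coding genes in 7 bins of transcript length in nucleotides, as deposited (circles) and after adjustment for length and GC content (squares). As deposited it climbs from -0.54 to 0.36, and after adjustment it lies between -0.11 and 0.01.

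Gene lists fixed in advance were tested with limma's fry, which asks whether the members of a list move on balance one way and does not compare a list with other genes. It called 9 of the 32 lists, but 4 without FGR 6, FGR 8 or FGR 9 and 3 without FGR 10. With camera and an estimated correlation between members, 0 lists were called, and 1 list, uterine epithelium, had an unadjusted p under 0.05. Of all 13183 tested genes 2583 were called higher. That share was 32.3% among coding genes of 4000 to under 6000 nucleotides and 50.2% among those of 6000 or more. The angiogenic list had 16 of 52 tested members called higher and 1 lower, 16 and 1 adjusted over the list alone, with a median log2 fold change of 0.30 (fry adjusted p = 0.00736, camera adjusted p = 0.741 with an estimated correlation). Its leading members were Angpt2, Kdr and Hif1a, the oxygen-responsive transcription factor gene, which rose from 21 ± 3.87 to 34.2 ± 1.76 FPKM (0.69, adjusted p = 0.00723) and had 0.33 after the length and GC adjustment. After the length and GC adjustment the median was 0.07 and the list was not called (fry adjusted p = 0.0824, range over the alternatives of fry 0.00102 to 0.208). With the same adjustment it was called without Control 1 (median 0.09, adjusted p = 0.031). As deposited its median was 0.20 without Control 1 (adjusted p = 0.00324).

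The list of invasion and matrix proteolysis had 18 of 43 members called, all of them higher, and 18 higher and 1 lower adjusted over the list alone (median 0.28, fry adjusted p = 0.00736, camera adjusted p = 0.741 with an estimated correlation). Among all tested genes 2583 of 13183 were called higher, and 50.2% of coding genes of 6000 nucleotides or more. Besides the protease inhibitor gene Serpine1 the called members included Adamts1, a metalloprotease gene of the ADAMTS family (0.92, adjusted p = 0.019), and Itgav, an integrin subunit gene (0.78, adjusted p = 0.00655). Itgav had 0.32 after the length and GC adjustment, and its call was lost when the Y-linked covariate was added (adjusted p = 0.0542, range over its alternatives 0.000309 to 0.0542). Adamts1 was not called after the length and GC adjustment (adjusted p = 0.0555) or with the Y-linked covariate (0.0531; range over its alternatives 0.00225 to 0.129). The list was the only one of the 32 called by fry after the length and GC adjustment of all samples, with a median of 0.07 (adjusted p = 0.0219) and 5 members called higher (885 of 13175 genes in that fit), and it was called by fry in each of the 28 alternatives (adjusted p from 0.00102 to 0.0368). The list of collagens and matrix was not called (fry adjusted p = 0.173, range over its alternatives 0.0293 to 0.83), though 11 of its 36 members were higher, also 11 adjusted over the list alone. Among them were the basement membrane genes Nid1 (0.94), Lamb1 (0.88) and Lamc1 (0.87), of which Nid1 was not called after the adjustment (adjusted p = 0.0679, range over its alternatives 0.00263 to 0.139).

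The oxidative phosphorylation, mitochondrially encoded and ribosomal protein lists lay lower in FGR placentas. Of 74 nuclear genes for oxidative phosphorylation subunits, 57 were called lower and 1 higher, 61 and 2 adjusted over the list alone (median -0.68, fry adjusted p = 0.0288). Atp5e fell from 37.9 ± 17.8 to 15.5 ± 1.51 FPKM, Uqcrq from 58.0 ± 18.3 to 26.6 ± 1.55 and Ndufa2 from 68.7 ± 28.1 to 31.0 ± 2.53. Of 13 mitochondrially encoded genes 9 were called, all lower, and 10 adjusted over the list alone (median -0.73, fry adjusted p = 0.00811), among them mt-Co3, which fell from 4140 ± 293 to 2180 ± 257 FPKM. Of 79 ribosomal protein genes 59 were called, all lower, and 67 adjusted over the list alone (median -0.65, fry adjusted p = 0.0385), led by Rps29 (-1.09), Rpl28 (-1.05) and Rpl36 (-1.05). Of all 13183 tested genes 1552 were called lower. Among coding genes outside these lists the share called lower was 49.1% under 1000 nucleotides and 32.7% from 1000 to under 1500, so many other short transcripts were also called lower. For each of these lists the camera adjusted p was 0.741 with an estimated correlation. After the length and GC adjustment their medians were -0.33, -0.46 and -0.31 and none was called by fry (adjusted p = 0.12, 0.12 and 0.182; highest over their alternatives 0.236, 0.29 and 0.381), with 25, 3 and 19 members still called lower. With the same adjustment but without Control 1, all 3 lists were called (medians -0.26, -0.62 and -0.20, fry adjusted p = 0.031 for each). Control 1 had the highest level in the oxidative phosphorylation and ribosomal protein lists, and without it their medians were -0.51 and -0.46 (fry adjusted p = 0.00415 and 0.00388). The oxidative phosphorylation list was not called without FGR 6 (adjusted p = 0.0605), FGR 8 (0.0563), FGR 9 (0.0571) or FGR 10 (0.0572), nor with the decidual covariate (0.0657). The ribosomal protein list was not called without Control 2 (0.0572), FGR 6 (0.0827), FGR 7 (0.07), FGR 8 (0.0817), FGR 9 (0.0796), FGR 10 (0.0914) or the averaged Control 3 and 5 (0.0625), nor with libraries rescaled to an equal sum (0.0832), the decidual covariate (0.0809) or the Y-linked covariate (0.0849). The 13 mitochondrially encoded genes made up 11.9% ± 2.41 of the summed FPKM in control and 8.68% ± 0.966 in FGR placentas (two-sided exact permutation test, p = 0.0159). Control 1, at 8.84%, lay within the FGR range of 7.38% to 10.1%. The groups also overlapped in the mean level of this list (two-sided exact permutation p = 0.0238, and 0.0571 without FGR 6, 8, 9 or 10, where the lowest possible is 0.0286). After the length and GC adjustment that permutation p was 0.0714. Quantile normalization ended the call of the mitochondrially encoded list (median -0.26, adjusted p = 0.29) and of mt-Co3 (-0.26, adjusted p = 0.253, range over its alternatives 0.000517 to 0.253).

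**Figure D3:**
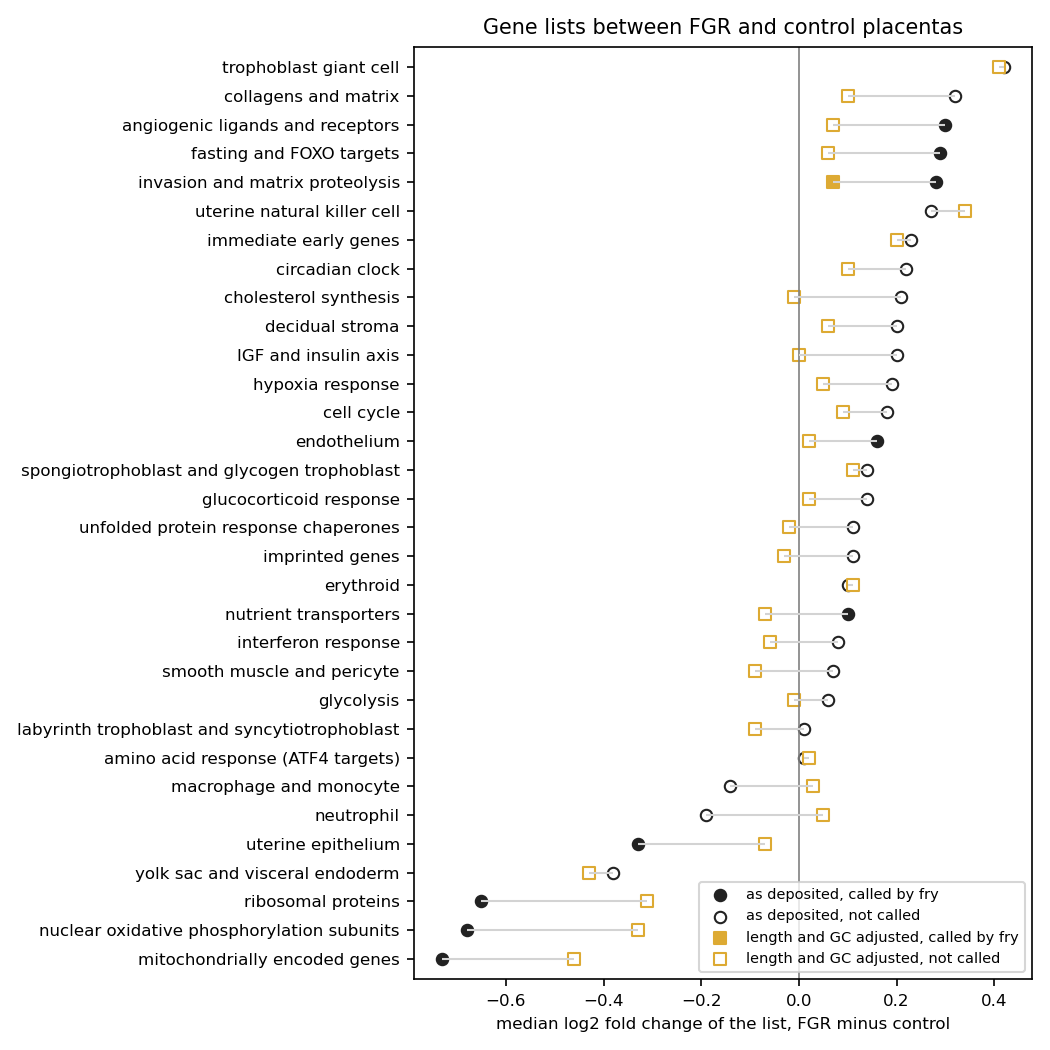
Median log2 fold change (FGR minus control) of the 32 gene lists as deposited (circles) and after adjustment for transcript length and GC content (squares), with filled symbols for lists called by fry at an adjusted p under 0.05. As deposited 9 lists are called, and after adjustment the list of invasion and matrix proteolysis is the only one.

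Among nutrient and stress lists, targets of fasting and FOXO factors had 8 of 24 members called higher and 1 lower, the same numbers adjusted over the list alone (median 0.29, fry adjusted p = 0.0385, camera adjusted p = 0.966 with an estimated correlation). Txnip, which restrains glucose uptake, rose from 42.8 ± 7.95 to 79.9 ± 3.56 FPKM (0.90, adjusted p = 0.00524), Foxo4 from 116 ± 14.1 to 191 ± 19.7 (0.72, adjusted p = 0.00641) and Fbxo32 had 0.61 (adjusted p = 0.024). Txnip (0.77) and Foxo4 (0.67) stayed called after the length and GC adjustment, whereas the list did not (median 0.06, adjusted p = 0.173, range over its alternatives 0.00346 to 0.381). Nor was this list called without Control 4 (adjusted p = 0.0659), FGR 6 (0.0898), FGR 7 (0.07), FGR 8 (0.0817), FGR 9 (0.0796), FGR 10 (0.11) or the averaged Control 3 and 5 (0.062). Without Control 1 it stayed called, with a median of 0.18 (0.00346). It was also lost with no filter (0.123), the decidual covariate (0.112) and the Y-linked covariate (0.086). Nutrient transporters had 8 of 46 members called higher and 1 lower, 7 and 0 adjusted over the list alone (median 0.10, fry adjusted p = 0.0451, camera adjusted p = 0.966 with an estimated correlation). The median of all tested genes was also 0.10, with 2583 of 13183 called higher, so these transporters rose no more than genes in general. Leading members were the endothelial lipase gene Lipg (1.00), the fatty acid transporter gene Cd36 (0.77) and, lower, Fabp3 (-0.87). Fabp3 had -0.57 without Control 1 and was then not called (adjusted p = 0.0522, range over its alternatives 0.00507 to 0.643). That list was lost without Control 2 (0.109), Control 4 (0.0684), FGR 6 (0.091), FGR 7 (0.0881), FGR 8 (0.0817), FGR 9 (0.0952) or FGR 10 (0.136), and its median turned to -0.07 after the adjustment (adjusted p = 0.663, range over its alternatives 0.00414 to 0.892). Its median was 0.20 without Control 2, 0.17 without FGR 8, 0.15 without FGR 9 and 0.19 without the averaged Control 3 and 5, the last still called (0.0478). It was also lost with no filter (0.0656), median-of-ratios factors (0.155), the decidual covariate (0.195) and the Y-linked covariate (0.13).

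Lists of other stress and growth programmes were not called by fry in the main fit. With libraries rescaled to an equal sum, fry called 13 lists that the main fit did not. Over the alternatives the lowest fry adjusted p was 0.0119 for the ATF4, glycolysis, IGF, imprinted and immediate early lists. It was 0.00696 for the chaperone, 0.0257 for the glucocorticoid and 0.0293 for the interferon list. The highest for these lists ran from 0.381 to 0.975. The hypoxia list was called without the averaged Control 3 and 5 (adjusted p = 0.0478, range over its alternatives 0.0108 to 0.551) and the clock list without Control 1 (0.0381, range 0.0257 to 0.774). Hypoxia genes had 4 higher and 2 lower of 29 (2 and 2 adjusted over the list alone, fry adjusted p = 0.152), including Egln3 (0.69) and Gbe1 (0.63). ATF4 targets of the amino acid response had 4 higher and 2 lower of 33 (4 and 2 adjusted over the list alone, fry adjusted p = 0.392), with the lipoprotein receptor gene Vldlr at 0.91 and Cebpb at -0.70. Chaperones of the unfolded protein response had 5 higher and 2 lower of 22 (6 and 2 adjusted over the list alone, fry adjusted p = 0.173), with Atf6 at 0.83 and Sec61b at -0.80. Glucocorticoid targets had 4 higher and 1 lower of 24 (4 and 0 adjusted over the list alone, fry adjusted p = 0.265), with Sgk1 at 0.81 and the metallothionein gene Mt2 at -0.98. Clock genes had 5 of 13 higher (5 adjusted over the list alone, fry adjusted p = 0.152), among them Arntl (0.55). Cholesterol synthesis genes had 4 of 24 higher, led by Hmgcr (0.90), and 0 adjusted over the list alone, with 7 higher at an unadjusted limma p under 0.05 (fry adjusted p = 0.587). Glycolysis had 1 of 20, Pfkp (0.34, and -0.10 after the length and GC adjustment), also 1 adjusted over the list alone (fry adjusted p = 0.392). Cell cycle genes had 4 higher and 1 lower of 48 (1 and 1 adjusted over the list alone, fry adjusted p = 0.56), with Ccne2 at 0.69 and the replication factor gene Gins2 at -0.87. Without FGR 7 the cell cycle counts were 1 higher and 3 lower, and without Control 1 they were 2 and 1. The IGF axis had 3 of 18 higher (3 adjusted over the list alone, fry adjusted p = 0.173), led by Pappa2 (1.01) and Igf2r (0.78). Imprinted genes had 7 higher and 2 lower of 41 (7 and 1 adjusted over the list alone, fry adjusted p = 0.295), of which Sfmbt2 rose from 13.8 ± 3.62 to 30.5 ± 3.91 FPKM (1.11, adjusted p = 0.0056). Interferon genes had 2 higher and 2 lower of 26 (2 and 2 adjusted over the list alone, fry adjusted p = 0.609), with Isg15 at -0.88 and Rsad2 at 0.64. Immediate early genes had 5 higher and 1 lower of 15 (5 and 1 adjusted over the list alone, fry adjusted p = 0.152), with Ccn1 at 0.83 and Fos at 0.63.

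Marker lists of cell types were set beside these changes, since whole placentas can differ in their makeup. The giant cell list had 5 higher and 2 lower of 27 members (4 and 1 adjusted over the list alone) and was not called (median 0.42, fry adjusted p = 0.199, range over its alternatives 0.0359 to 0.402). Its counts were 8 higher and 2 lower without Control 1 and 8 and 0 without FGR 7. With Control 3 and Control 5 as separate libraries they were 12 and 2. The endothelium list had 6 higher and 1 lower of 30 (6 and 0 adjusted over the list alone, median 0.16, fry adjusted p = 0.0292, camera adjusted p = 0.966 with an estimated correlation). With it rose Kdr, Pecam1 and Cdh5 (0.69). The share of endothelium members called higher was close to that of all tested genes (2583 of 13183), whose median was 0.10. The endothelium call was lost without Control 4 (0.0659) or FGR 10 (0.0572), and its median was 0.08 with median-of-ratios factors (adjusted p = 0.305) and 0.02 after the length and GC adjustment (adjusted p = 0.663, range over its alternatives 0.00113 to 0.681). With only genes of mean FPKM of at least 5 tested, it was -0.07 (adjusted p = 0.628). Quantile normalization (0.324), the decidual covariate (0.0779) and the Y-linked covariate (0.0709) also ended the endothelium call. Uterine epithelium had 2 of 14 members called, both lower, and 0 adjusted over the list alone, with 1 higher and 2 lower at an unadjusted limma p under 0.05 (median -0.33, fry adjusted p = 0.0385, camera adjusted p = 0.741 with an estimated correlation). These were Wfdc2 (-0.90) and the keratin gene Krt7 (-0.35). Wfdc2 had -0.58 without Control 1 and was then not called (adjusted p = 0.0658), and it lost its call in 19 of its 28 alternatives (range 0.00914 to 0.724). The list call was lost without Control 2 (0.177), FGR 6 (0.091), FGR 8 (0.0817), FGR 9 (0.114), FGR 10 (0.0914) or the averaged Control 3 and 5 (0.116), and after the adjustment the median was -0.07 (adjusted p = 0.462, range over its alternatives 0.00128 to 0.803). It was also lost with no filter (0.123), libraries rescaled to an equal sum (0.326), quantile normalization (0.0513), the decidual covariate (0.083) and the Y-linked covariate (0.0849).

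Labyrinth and syncytiotrophoblast markers had 5 higher and 3 lower of 28 (4 and 2 adjusted over the list alone, fry adjusted p = 0.704, range over its alternatives 0.0476 to 0.989). Gcm1, the transcription factor that starts syncytiotrophoblast formation, rose from 3.06 ± 1.33 to 8.07 ± 2.25 FPKM (log2 fold change 1.19, adjusted p = 0.0121), and Tjp1 was at 0.77. Spongiotrophoblast and glycogen cell markers had 2 of 28 higher, Aldh1a3 (0.80) and Pcdh12 (0.54), and 0 adjusted over the list alone, with 2 higher and 1 lower at an unadjusted limma p under 0.05 (fry adjusted p = 0.816). Decidual stroma had 2 higher and 1 lower of 25 (2 and 1 adjusted over the list alone, fry adjusted p = 0.442), with the steroid synthesis gene Cyp11a1 at 0.83, Bmp8a at 0.71 and Gadd45g at -0.74. Uterine natural killer cell markers had 3 of 10 higher (3 adjusted over the list alone, fry adjusted p = 0.306), Itga2 (0.77), Il2rb (0.61) and Eomes (0.43). Macrophage markers had 1 higher and 3 lower of 16 (1 and 0 adjusted over the list alone, fry adjusted p = 0.418), with Csf1r at 0.60 and C1qb at -0.60. Neutrophil markers had 1 of 7, Cxcr2 (0.44), and 0 adjusted over the list alone, with 1 higher at an unadjusted limma p under 0.05, and a median of -0.19 against an upward fry direction (fry adjusted p = 0.953). Erythroid markers had 2 of 28 called, both lower, the adult alpha globin copies Hba-a1 (-1.01) and Hba-a2 (-0.98), whose reads cannot be told apart. Adjusted over the list alone the erythroid count was 0, with 3 lower at an unadjusted limma p under 0.05, and the median of 0.10 stood against a downward fry direction (fry adjusted p = 0.953). Yolk sac markers had 0 of 29 called by limma over all genes and 0 adjusted over the list alone, with 1 lower at an unadjusted limma p under 0.05 (fry adjusted p = 0.816). Car4 and Slc13a4 had log2 fold changes of -0.40 and 0.17. Smooth muscle and pericyte markers had 0 of 13 and 0 adjusted over the list alone, with 1 higher at an unadjusted limma p under 0.05 (fry adjusted p = 0.704), and Mcam and Notch3 had log2 fold changes of 0.31 and 0.32.

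Placentas also differed in ways the labels do not name. The yolk sac transcript Afp ran from 24.8 to 3892 FPKM in control and from 74.2 to 5924 in FGR placentas. Summed Y-linked transcripts were at 0.27 to 1.59 FPKM in Control 1, 3 and 5 and at 0.93 in FGR 7, where Xist was high, and at 15.9 to 23.8 in the other 6 libraries. With the Y-linked level as a covariate 2336 genes and 4 lists were called, the angiogenic (adjusted p = 0.00138), invasion (0.00138), oxidative phosphorylation (0.0228) and mitochondrially encoded (0.0163) lists. Of the 93 called genes among the 103 genes named by rule, 64 stayed called with each library, and the averaged Control 3 and 5, left out in turn, 44 after the length and GC adjustment, 64 with the Y-linked covariate and 41 in all of these settings. With the adjustment and the Y-linked covariate together 24 of the 93 stayed called, with no filter 58 and with the decidual covariate 71, and without the averaged Control 3 and 5 12 were lost. The 41 include Prl7a1, Prl3d1, Serpine1, Tfpi, Angpt2, Kdr, Hif1a, Txnip, Foxo4, Sfmbt2, Gcm1, Gp1bb, Gins2, mt-Nd3, Uqcrq and Rpl28. Another 29 named genes lost their call without at least 1 library or the averaged Control 3 and 5, with adjusted p from 0.0505 to 0.115: Egln3, Anln, Cebpb, Fbxo32, Mt2, Bhlhe40, Hsd17b7, Ldlr, Rrm1, Fabp3, Pappa2, Igf2r, Irs2, Ccn1, Klf4, Fos, Aldh1a3, Pcdh12, Tfrc, Cyp11a1, Gadd45g, C1qb, Folr2, Cxcr2, Hba-a1, Hba-a2, Wfdc2, Krt7 and Plau. Of these, Igf2r and Gadd45g lost it only without FGR 9 (adjusted p = 0.0513 and 0.053) and Cyp11a1 only without Control 2 (0.0512). Named genes called as deposited but not after the length and GC adjustment were mt-Ts1, mt-Tg, Adamts1, Egln3, Anln, Vldlr, Cebpb, Atf6, Fbxo32, Mt2, Arntl, Nr1d2, Bhlhe40, Hmgcr, Hsd17b7, Ldlr, Pfkp, Rrm1, Fabp3, Cd36, Pappa2, Igf2r, Irs2, Peg3, Isg15, Bst2, Rsad2, Nid1, Klf4, Aldh1a3, Pcdh12, Tjp1, Tfrc, Cdh5, Cyp11a1, Gadd45g, Itga2, Il2rb, Eomes, Csf1r, C1qb, Folr2, Cxcr2, Hba-a1, Hba-a2, Wfdc2, Rps29, Tek and Plau.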

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

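The tests chosen after the result was seen were the matched comparison, the length and GC adjustment, the range of the abundant giant cell members, the count of FGR placentas with spermatid transcripts and the use of the fits without Control 1 and with the Y-linked covariate to weigh explanations, though these fits had been planned, and Control 3 and Control 5 were averaged after the pair was seen.

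Spermatid transcripts appeared in FGR 7, in genes below the expression filter. The summed FPKM of 8 spermatid genes, led by Tnp2 at 10.7, Prm2 at 9.52 and Tnp1 at 8.03, was 43.26 in FGR 7 and 2.27 in FGR 6, against 0.04 to 0.19 in the controls and at most 0.08 in FGR 8, 9 and 10. If reads from a testis sample had entered this library, other spermatid genes should be highest there: of 25 spermatid genes not used to find the pattern, of which 1 reaches 1 FPKM in any control, 20 were highest in FGR 7, where 2.5 are expected by chance, so carry-over from testis is a candidate source. The sum lay above every control in 2 of the 5 FGR placentas, but these are the genes in which the pattern was seen, so a response of placentas to the diet stays open as untested. Transcripts of pancreas and intestine were highest in FGR 7 for 14 of 22 genes, and 5 of the 22 reach 1 FPKM in a control. Among the 14, Vil1 was at 17.56 FPKM in FGR 7 but also at 14.9 in Control 5, and Fabp2 at 5.26 and 2.65. The yolk sac transcript Afp was likewise highest in FGR 7 (5924 FPKM, against 3892 in Control 5). Yolk sac was not tested as a source of these transcripts, and their source stays open. Without FGR 7, 3641 genes were called.

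The called gene lists lie along the length trend, which may account for part of their change, but against genes matched on length, GC content and level, the oxidative phosphorylation list differed by -0.30 between the groups (-0.20 without Control 1) and the invasion list by 0.16, and the placentas of the groups did not overlap in either (two-sided exact permutation p = 0.00794). The unmatched differences were -0.58 (SD 0.28 in control, 0.11 in FGR placentas) and 0.32 (SD 0.12 and 0.06). The trend, as far as this matching captures it, is thus argued against as their whole cause but not as a part. Length was that of the longest GENCODE M21 transcript, and the annotation behind the FPKM is unknown. After the smooth adjustment other coding genes under 1000 nucleotides still had a median of -0.11, so an uncaptured part of the trend may remain. For ribosomal proteins (-0.32 matched against -0.61 before) and the angiogenic list (0.12 against 0.27) the groups overlapped in the matched comparison (two-sided exact permutation p = 0.0238) but not after the smooth adjustment (-0.35 and 0.11, p = 0.00794), and with these tests differing the trend and the diet cannot be told apart. Without Control 1 the ribosomal difference was -0.18 matched (two-sided exact permutation p = 0.0714) and -0.21 after the smooth adjustment. The matched p was also over 0.05 for ribosomal proteins without FGR 6, 7, 8 or 10 (0.0571 each) and for the angiogenic list without Control 2 or 4 (0.0536), Control 3 and 5 (0.0714) or FGR 6, 8, 9 or 10 (0.0571). Without 1 FGR sample no p under 0.0286 is possible, and the ribosomal differences stayed at -0.30 or -0.31 without FGR 6, 7, 8 or 10. The matched comparison was chosen after the smooth adjustment had ended the fry calls of the oxidative phosphorylation (difference -0.34), ribosomal protein and angiogenic lists with Control 1 in the fit, where the SD among controls was 0.22, 0.28 and 0.03 (before 0.28, 0.36 and 0.10); without Control 1 the adjusted lists were called (adjusted p = 0.031 each), and Control 1 alone is argued against, since without it the unadjusted oxidative phosphorylation median was -0.51.

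Giant cell transcripts were called higher for 5 of 27 members and lower for 2, and the list was not called (fry adjusted p = 0.199, range over its alternatives 0.0359 to 0.402). Its difference of 0.39 left the groups overlapping (two-sided exact permutation p = 0.119) and was 0.23 without the averaged Control 3 and 5. Called members were 8 higher and 2 lower without Control 1, and 8 and 0 without FGR 7. They were 12 and 2 with Control 3 and Control 5 kept separate. A like increase of all giant cell subtypes alone would raise the list's abundant members alike. The log2 fold changes of the 4 most abundant spanned 1.70: Prl3b1 0.06, Ctsj 0.72, Prl8a9 -0.20 and Prl2c3 1.50, with SE of 0.36, 0.29, 0.42 and 0.22. Because the list pools markers of several subtypes, this span cannot tell whether the share of some of them rose. With the Y-linked covariate the list median was 0.29, from 0.42, and 4 of its 5 members called higher stayed called. After the length and GC adjustment it was 0.41 and all 5 stayed called, with 0 lower calls in either fit. The higher calls of these members thus did not rest on the fitted length trend, and most did not rest on the Y-linked level. The list itself was called in neither fit (fry adjusted p = 0.381 with the Y-linked covariate and 0.182 after the adjustment). Only FGR 7 among the FGR placentas was low in Y-linked transcripts. These fits therefore cannot weigh fetal sex or the length trend as causes for the list. A change within giant cells, or more of the subtype that makes Prl3d1 and Prl2c3, may remain, as does the diet, and none of these was tested.

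Chance is argued against for the number of called genes. Of 100 of the 126 splits of the 9 samples into groups of 4 and 5, only 1, the real one, gave as many as 4135. That 1 in 100 is the lowest share these draws can give. The highest of the others gave 529, with FGR 7 grouped with the controls. Many calls lie along the length trend, so they are not independent of each other. Dams are not labelled, and the splits do not tell what caused the difference.

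Chance puts about 1 in 20 groups of samples past the limit used for single values. Single samples far from the rest of their group were found in 20 of 220 sets of values, where chance gives 11. Control 1 held 9 of them among named genes measured in FPKM: Adamts1 at 1.82 (others 4.18 to 4.82), Cebpb at 180 (91.3 to 100), Sec61b at 121 (80.9 to 86.2), Sel1l at 9.76 (14.1 to 14.7), Txnip at 31.0 (45.5 to 48.1), Atp5e at 64.5 (26.4 to 30.4), Fabp3 at 434 (185 to 195), Irs2 at 4.67 (7.22 to 7.52) and Rps29 at 351 (131 to 140). FGR 8 was apart for Sec61b at 45.7 (53.7 to 54.4), Atp5e at 12.8 (15.9 to 16.4), Ndufa2 at 26.6 (31.2 to 32.9), Slc13a4 at 40.2 (23.7 to 24.2) and Rpl28 at 101 (124 to 129). FGR 7 was apart for mt-Nd3 at 350 (234 to 258) and Pfkp at 12.2 (14.5 to 15.4), FGR 10 for mt-Tg at 3.55 (4.93 to 5.55) and Sgk1 at 26.8 (15.4 to 17.9), and the mean of Control 3 and 5 for Eomes at 1.03 (0.59 to 0.65). In FGR 6 globins made up 5.88% of the summed FPKM, against 3.50% to 3.93% in the other FGR placentas.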

How the results depend on the processing

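Among the fits compared in this section, those with the length and GC adjustment and those without 2 or more libraries at once were chosen after seeing the data. So was the averaging of Control 3 and Control 5, which had been planned as separate libraries. The 4135 calls (2583 higher, 1552 lower) and 9 called lists stayed within 1.5 times with pseudocounts of 0.1 and 0.5, median-of-ratios factors, quantile normalization, robust moderation, no intensity trend, library weights and Control 3 and Control 5 kept separate as planned (4780 calls). Without the filter 2601 genes were called, 1646 higher and 955 lower, with more genes tested. With mean FPKM of at least 5, 1630 genes were called higher, with fewer tested, and the endothelium median turned to -0.075. With libraries rescaled to an equal sum, 5420 genes were higher, 706 lower and 20 lists called, since FGR libraries had the lower sums. The Y-linked covariate gave 2336 calls (1423 higher, 913 lower) and 4 lists, and the decidual covariate 2611 calls (1541 higher) and 3 lists; the cause was not tested. Camera called 0 lists with an estimated correlation and 5 with the preset. The length and GC adjustment gave 1735 calls (885 higher, 850 lower) and 1 list, 1736 (837 and 899) and 5 lists without Control 1 (invasion, angiogenic, oxidative phosphorylation, mitochondrially encoded and ribosomal protein), and 711 (392 and 319) and 1 list with the Y-linked covariate. In these 3 fits the log2 fold change of Pfkp turned to -0.102, -0.036 and -0.114 and the nutrient transporter median to -0.073, -0.044 and -0.07; the cause was not tested. Leaving out 1 library gave 2522 to 4235 calls, 1523 to 2652 higher and 999 to 1583 lower, and 3 to 10 lists; leaving out Control 3 or Control 5 kept 9 samples, as these are averaged, and leaving out both gave 3423 calls and 7 lists. The exact Wilcoxon test called 3986 genes. Its smallest p for 4 against 5 samples is 0.0159, so its calls fell on genes whose groups did not overlap. The 1262 genes with ties were left out of it. No paired analysis was possible because the groups share no replicate numbers, and what depth limits could not be assessed from FPKM.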
